A study of Mus musculus with 18 samples.

How the data were processed

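RNA of 200 sorted cells per library was amplified with a SMART-seq kit, per the labels' protocols, and sequenced in 18 libraries of 6 groups with 3 libraries each. The deposited table holds gene counts as whole numbers. Per the submitters' processing notes, reads were trimmed with fastp 0.23.0, aligned to mm10 with HISAT2 2.1.0 and counted per gene with featureCounts of Subread 1.6.5. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Genes that overlap, antisense genes and genes with near-identical copies are therefore uncertain in level. Every column of the table belonged to a sample, with 0 columns left over. Of 46078 genes in the table, 45143 were matched to a symbol, and the 935 without one held 0.0544% of the counts. Coordinates were taken from the GENCODE annotation of the same genome build.

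Genes were kept with edgeR's filterByExpr at its minimum count of 10, which left 14714. Libraries were scaled by the TMM method, and a quasi-likelihood model with a mean for each of the 6 groups was fitted to all 18 libraries, which share the estimate of spread, with edgeR 4.0.16 in R 4.3.3. The common biological coefficient of variation was 0.862, with 4.04 prior degrees of freedom. RARa403 was compared with control in liver ILC1s, liver NK cells and spleen ILC1s, control liver ILC1s with control liver NK cells, and control spleen ILC1s with control liver ILC1s. The RARa403 effect was also compared between liver ILC1s and liver NK cells and between spleen and liver ILC1s, as interaction contrasts. P-values were adjusted within each comparison by the Benjamini-Hochberg method with a threshold of 0.05. Levels are log2 CPM with a prior count of 2. Standard errors were derived from the fold change and its F statistic. The p-values measure the spread between libraries, and the labels do not say which libraries share an animal.

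Gene lists were written from general knowledge of the cell types and processes, 31 lists with 711 entries, covering cell type signatures, cell processes, markers of other cells and classes of transcripts. In each comparison 30 of them were tested, each with at least 3 tested genes, by camera with a preset correlation of 0.01 between genes. Camera was run again with an estimated correlation, and fry was run as well, both from limma 3.58.1. Adjustment was over the lists of a comparison. The lists, the comparisons, the alternatives, the main test and the rule for naming genes were fixed before the data were examined.

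Genes are named by that rule. In a comparison of groups these are, among genes past the threshold with a mean of at least 3 log2 CPM in the higher group and no overlap of the groups, the 10 largest increases and the 10 largest decreases, leaving out predicted and unnamed genes. Interactions follow it with up to 5 genes per direction and no condition on overlap. Where no gene passed, up to 4 genes with the smallest p among those at the same minimum level, again without predicted and unnamed genes, are given as values. Rara, Rarb, Rarg, Ncr1, Itga1, Itga2, Il7r, Eomes, Tbx21, Zfp683, Cxcr6 and Bcl2 were always reported. For each list described, up to 4 members past the threshold, or else up to 2 with the smallest p, are named. Genes called in the same direction in several RARa403 comparisons would have been named too. Any other gene is said to have been chosen after its values were seen. Some genes that the rule names are not reported here.

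Alternatives fixed in advance were DESeq2 1.42.0, RLE scaling factors, no filter on low counts, only the groups compared, the replicate number as a block, the opening number of the description code as a term, limma-voom with quality weights, a log2 fold threshold of 1, and leaving out each library in turn. Alternatives chosen after seeing the data were liver NK RARa403 library 1 left out of the shared fit, replicates 2 and 3 only, and a contrast of the mean RARa403 effect over the 3 populations.

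The steps were tested on simulated data before use. Counts for 14714 genes were drawn from the means and library sizes of the real samples, with 200 genes changed by known folds. For control liver ILC1s against control liver NK cells edgeR recovered 16% of genes changed 4-fold and 42% of those changed 16-fold, with 2 false calls among 60. For RARa403 against control, edgeR recovered 16% and 47% in liver ILC1s, 14% and 41% in liver NK cells, and 18% and 50% in spleen ILC1s. For control spleen against control liver ILC1s it recovered 11% and 48%. DESeq2, an alternative fixed in advance, made 54 to 74 false calls among 150 to 177 in the same simulations. It recovered 30 to 38% of genes changed 4-fold and 59 to 70% of those changed 16-fold. Depth per library and the level that 3 counts represent are given with the data.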

Results

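Gene expression was measured by SMART-seq, which amplifies full-length cDNA from small inputs, in 18 bulk libraries of 200 sorted cells each from C57BL/6 mice 8 weeks old. The cells were liver type 1 innate lymphoid cells (ILC1s, tissue-resident lymphocytes that make interferon-γ), liver natural killer (NK) cells, which circulate and kill target cells, and spleen ILC1s. Each population was taken from control mice with Ncr1-Cre, which expresses Cre recombinase in cells that make the receptor NKp46, and from mice that also carried RARα403 at the Rosa26 locus. RARα403 is a truncated retinoic acid receptor α that acts as a dominant negative, and Cre switches it on. This gave 6 groups of 3 libraries, called liver ILC1, liver NK and spleen ILC1, control or RARa403, replicates 1 to 3. The question in the title of the series is whether retinoic acid receptor activity is needed to maintain ILC1s. The labels do not say which animals gave which libraries, so every p-value measures the spread between these libraries. Both sexes were present: Xist, the transcript of the inactive X chromosome, had 596 to 1404 counts in control library 3 and RARa403 library 2 of each population and at most 28 in the other 12 libraries. ILC1s had been gated on CD49a, low CD49b and the interleukin-7 receptor, and both cell types on NKp46. Differences in Itga1, Itga2 and Il7r between ILC1s and NK cells therefore follow from the sort and are no finding. In the RARa403 comparisons both genotypes had passed the same gate, which limits differences in the genes of its markers.

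The deposited table gave 3452279 to 9038767 counts per library. Liver ILC1 libraries 1, 2 and 3 held 7184888, 3452279 and 4549841 counts in control and 6087298, 6686951 and 6809570 in RARa403 cells. Liver NK libraries held 6421894, 8995720 and 5727907 in control and 6052296, 9038767 and 5852815 in RARa403 cells. Spleen ILC1 libraries held 8214734, 7093353 and 5445189 in control and 6276036, 5949662 and 7344750 in RARa403 cells. A level of 3 counts, used as the floor per library, came to 0.334 to 0.860 CPM, counts scaled to the library total, and 14307 to 19211 genes had at least a count. Liver NK RARa403 library 1 stood apart from the other 17 libraries. Its mean Pearson correlation with the other libraries of its group, across genes, was 0.633. Genes annotated as ribosomal RNA, with Gm26917, CT010467.1, Gm23935 and Lars2 added, held 3.55% of its counts, against at most 0.387% elsewhere. Lars2 alone held 0.683% of its counts and Gm26917 0.648%. Of 2735 genes above 50 CPM in each of the other 17 libraries, 192 (7.02%) had 3 counts or fewer there, while the same measure gave 0 genes for each of the other libraries. For this measure CPM were scaled to the library total alone. That measure was chosen after the values were seen.

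The genes of the 3 retinoic acid receptors were examined first in every library, because the mice carry an altered receptor. Rara (ENSMUSG00000037992, mm10 chromosome 11, 98927818 to 98974942, protein coding) lay between 4.51 and 5.81 log2 CPM in 17 libraries and at 8.75 in liver NK RARa403 library 1. Group means in control and RARa403 cells were 5.22 ± 0.44 and 5.51 ± 0.18 in liver ILC1s, 4.85 ± 0.25 and 6.12 ± 2.30 in liver NK cells, and 5.39 ± 0.18 and 5.64 ± 0.20 in spleen ILC1s (SD, n = 3). The Rara counts thus did not mark the RARa403 libraries, and how reads of the insert were counted is not given in the sources used here. Gt(ROSA)26Sor (ENSMUSG00000086429), the noncoding transcript of the locus that holds the insert, was examined after the values had been seen. It had 104 to 1260 counts in the 9 control libraries and at most 10 in RARa403 libraries 2 and 3 of the 3 populations. RARa403 library 1 was at 5.98 log2 CPM in liver ILC1s and 5.83 in spleen ILC1s, within the range of the controls, 4.51 to 7.25. It had 0 counts in liver NK cells, the library with the missing transcripts. Gm13394, a processed pseudogene also picked after its values were seen, had 452 to 1009 counts in RARa403 libraries 2 and 3 of each population. It had 19 to 64 counts in the controls and in RARa403 library 1 of each population. The labels do not give the number of inserted copies per mouse, so the counts of RARa403 library 1 do not settle its genotype. Counts and called lists of the RARa403 comparisons were therefore also obtained with replicates 2 and 3 only.

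**Figure D1:**
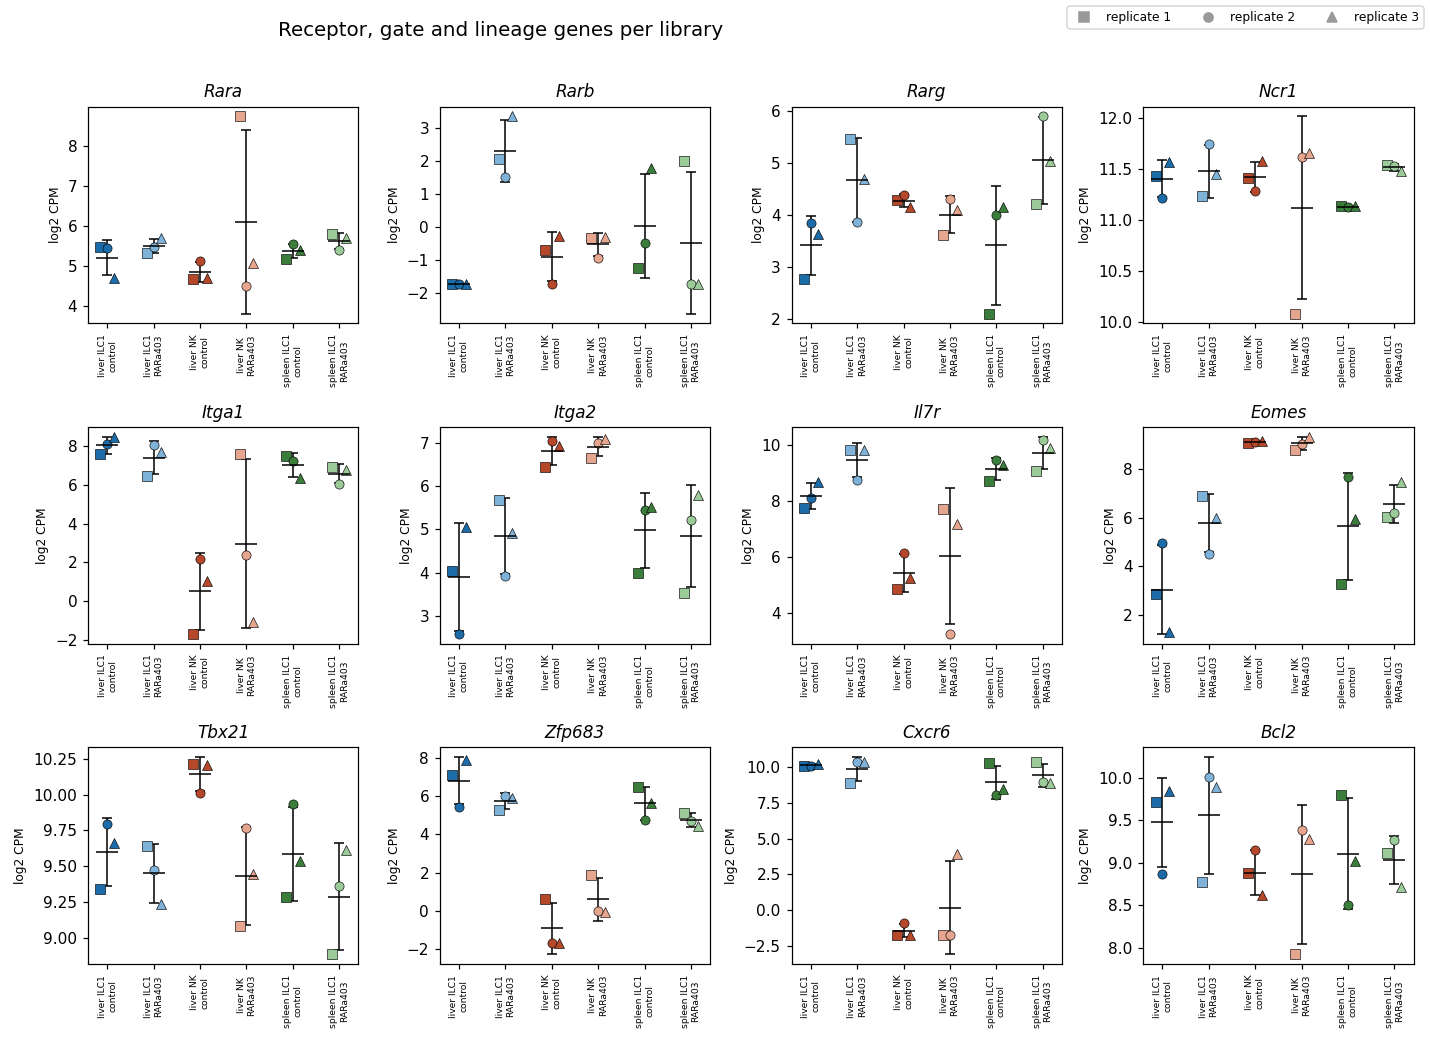
Levels of the 12 genes fixed in advance in log2 CPM (y axis, prior count 2) in the 6 groups (x axis); points are the 3 libraries of a group, and lines with bars the mean ± SD. Cxcr6 and Zfp683 are high in both ILC1 populations and Eomes in NK cells, while Rara differs little apart from liver NK RARa403 library 1 at 8.75.

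Control liver ILC1s and control liver NK cells were compared to show what separates the cell types before RARa403 is expressed. ILC1s carried far more transcript of Cxcr6, a chemokine receptor that retains lymphocytes in the liver, with 10.13 ± 0.09 log2 CPM against −1.44 ± 0.45 in NK cells (SD, n = 3; log2 fold change 13.30, SE 1.88, adjusted p = 0.00426). Zfp683, which encodes Hobit, a transcription factor of tissue-resident lymphocytes, was also higher (log2 fold change 8.39, SE 1.20, adjusted p = 0.00426). NK cells carried more Eomes, a T-box transcription factor needed for NK cell maturation, with 9.11 ± 0.05 log2 CPM against 3.04 ± 1.82 in ILC1s (log2 fold change −5.42, SE 1.06, adjusted p = 0.0277), and more Itgam, which encodes CD11b (log2 fold change −3.80, SE 0.60, adjusted p = 0.0105). Tbx21, the T-box factor that both cell types need, was 9.60 ± 0.23 log2 CPM in ILC1s and 10.14 ± 0.12 in NK cells and did not pass the test (log2 fold change −0.53, adjusted p = 0.628). Of the other genes fixed in advance, neither the sorting markers Itga1 (7.06, adjusted p = 0.0730), Itga2 (−2.63, adjusted p = 0.113), Il7r (2.69, adjusted p = 0.150) and Ncr1 (−0.01, adjusted p = 1) passed, nor Bcl2 (0.63, adjusted p = 0.846), Rara (0.40, adjusted p = 1), Rarg (−0.81, adjusted p = 0.932) or Rarb, with no counts in ILC1s (adjusted p = 0.737). In all, 89 genes passed an adjusted p of 0.05, 63 higher and 26 lower in ILC1s, and 78 of them were protein coding. Their median absolute log2 fold change was 4.46.

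The other genes with the largest differences were of several kinds. Genes with no counts in the 3 NK control libraries were P2rx7, an ATP-gated channel (at least 174-fold higher in ILC1s, adjusted p = 0.00238), Sept8, a septin (at least 94.8-fold, adjusted p = 0.000242), and Ccdc136 (at least 122-fold, adjusted p = 0.00692). The same held for Cd200r2 (at least 393-fold, adjusted p = 0.0156) and Adam19, a metalloproteinase (at least 97.4-fold, adjusted p = 0.0248). It also held for Tcrg-C2, a constant region of the γδ T cell receptor (at least 51.5-fold, adjusted p = 0.0116), and Serpinb1a (at least 44.5-fold, adjusted p = 0.0326). These bounds set the NK cells at 3 counts per library and cover counting error only, as do the floors. Mmp9, a gelatinase, and Ckb, a creatine kinase, were higher by 12.10 (SE 2.30, adjusted p = 0.0237) and 11.09 (SE 1.97, adjusted p = 0.0156) on the log2 scale. Lower in ILC1s were Mcam, which encodes the adhesion molecule CD146 (at least 105-fold lower, adjusted p = 0.0278), and Zeb2, a transcription factor of late NK maturation (log2 fold change −4.46, adjusted p = 0.0461). So were Fbxl2 (−4.13, adjusted p = 0.0326), Nrarp (−3.87, adjusted p = 0.0248) and Sh2d1a, the signalling adaptor SAP (−3.11, adjusted p = 0.0232). The Ly49 receptor genes Klra8 (log2 fold change −11.33, SE 1.82, adjusted p = 0.0113), Klra4 (−10.91, SE 1.98, adjusted p = 0.0172) and Klra10 (−6.36, SE 1.37, adjusted p = 0.0461) were lower too. They belong to a family of near-identical neighbours on chromosome 6, where the counting could have split reads, so the level of each is uncertain.

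In mm10 the genes lie as follows. Cxcr6 (ENSMUSG00000048521) spans chromosome 9 from 123806475 to 123811760 and Eomes (ENSMUSG00000032446) chromosome 9 from 118478212 to 118486132. Zfp683 (ENSMUSG00000049410) spans chromosome 4 from 134053838 to 134058996, Itgam (ENSMUSG00000030786) chromosome 7 from 128062640 to 128118491, Sept8 (ENSMUSG00000018398) chromosome 11 from 53519257 to 53549565, and P2rx7 (ENSMUSG00000029468) chromosome 5 from 122643911 to 122691432. Klra8 (ENSMUSG00000089727) spans chromosome 6 from 130115226 to 130129898 and Tbx21 (ENSMUSG00000001444) chromosome 11 from 97098071 to 97115331. Each of them is annotated as protein coding.

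**Figure D2:**
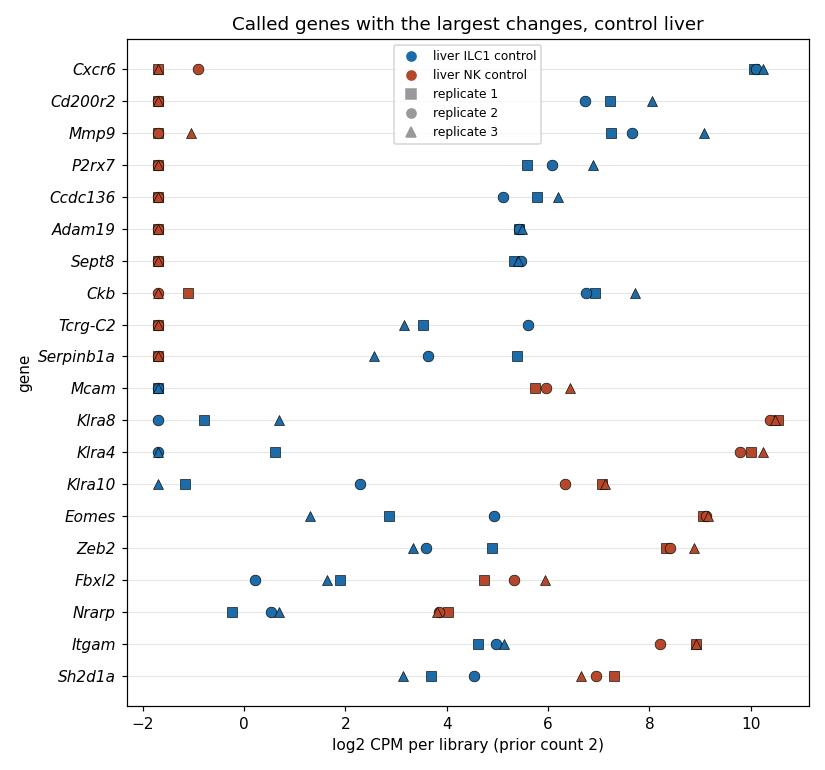
Levels in log2 CPM of the 20 genes with the largest differences between control liver ILC1s and control liver NK cells; points are the 3 libraries of each cell type. The genes were chosen by size of difference without overlap, and Cxcr6 lies at 10.13 ± 0.09 in ILC1s and −1.44 ± 0.45 in NK cells.

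Gene lists fixed in advance followed the same division. Of 30 tested genes of an ILC1 list, 10 were higher in ILC1s, 0 lower and 20 not past the threshold, with Socs2, a feedback inhibitor of cytokine signalling (log2 fold change 4.68, adjusted p = 0.000646), Tmem176b (5.47, adjusted p = 0.0123), Cxcr6 and Zfp683 among them. Adjusted over the list alone, 23 were higher and 1 lower. Of 29 NK list genes 7 were lower, 0 higher and 22 not past it, including Irf8, a transcription factor (−2.35, adjusted p = 0.0212), and 22 were lower adjusted over the list alone. The ILC1 list was higher as a whole (median log2 fold change 2.83, adjusted p = 3.74e-42) and the NK list lower (median −3.80, adjusted p = 6.59e-42), with adjusted p = 0.000482 and 0.00112 with an estimated correlation. These lists name genes known from such cells, and 23 of the ILC1 list and 13 of the NK list also stand in other lists. Of 17 cytokine and chemokine genes 3 were higher and 14 not past the threshold (7 higher adjusted over the list alone). The 3 were Ltb, a lymphotoxin subunit (2.56, adjusted p = 0.0136), Il2 (7.25, adjusted p = 0.0356) and Xcl1, a chemokine for cross-presenting dendritic cells (2.51, adjusted p = 0.0382). That list was higher as a whole (adjusted p = 9.54e-08, and adjusted p = 0.00402 with an estimated correlation). Of 18 T cell marker genes 2 were higher and 16 not past the threshold (11 higher and 1 lower adjusted over the list alone). The 2 were Trbc2, a T cell receptor β constant region (1.85, adjusted p = 0.00413), and Cd3e (6.93, adjusted p = 0.0264), although both cell types had been gated as CD3-negative. The T cell list was higher as a whole (adjusted p = 1.62e-10, and adjusted p = 0.00195 with an estimated correlation). Its lowest mean in a control ILC1 library was 4.11 log2 CPM and its highest in a control NK library 2.64.

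Further lists passed with the preset correlation but not with an estimated one. Of 19 cytotoxic effector genes 3 were lower in ILC1s and 16 not past the threshold (2 higher and 4 lower adjusted over the list alone). The 3 were Gzma, which encodes granzyme A (−2.91, adjusted p = 0.0248), Prf1, which encodes perforin (−2.60, adjusted p = 0.0400), and Serpinb9, a granzyme B inhibitor (−1.69, adjusted p = 0.0231). The list's own test gave adjusted p = 0.000568, and adjusted p = 0.323 with an estimated correlation. Of 32 cytokine receptor and signalling genes 1 was higher, Socs2, and 2 lower, Il10ra (−1.61, adjusted p = 0.0116) and Il18rap (−1.54, adjusted p = 0.0401), with 7 higher and 4 lower adjusted over the list alone. This list gave adjusted p = 0.0155 with the preset correlation, adjusted p = 0.0939 with an estimated correlation and adjusted p = 0.0996 without liver NK control library 1. By fry, which tests whether the genes of a list move on balance in a single direction, it passed (adjusted p = 0.0193). Fry called 5 lists in this comparison, this list and the 4 that passed with an estimated correlation, and 0 in each of the other comparisons. Lists with 0 called members were higher in ILC1s too. These were proliferation (adjusted p = 0.000684, and adjusted p = 0.718 with an estimated correlation), and interferon response (adjusted p = 9.12e-05, and adjusted p = 0.323 with an estimated correlation). The others were B cell (adjusted p = 0.00182, and adjusted p = 0.517 with an estimated correlation) and hepatocyte markers (adjusted p = 0.000227, and adjusted p = 0.517 with an estimated correlation) and the markers of ILC2s and ILC3s (adjusted p = 0.0473, and adjusted p = 0.352 with an estimated correlation). Proliferation was lost without liver NK control library 3 (adjusted p = 0.135). Hepatocyte markers were lost without liver ILC1 control library 1 (adjusted p = 0.161), whose hepatocyte mean was 3.30 log2 CPM against −0.56 and −0.45 in the other liver ILC1 controls. The ILC2 and ILC3 list was lost without liver ILC1 control library 1 (adjusted p = 0.252) and liver NK control libraries 1 and 2 (adjusted p = 0.121 and 0.0729). Outside the lists that passed, Cd7 (2.53, adjusted p = 0.00061), Cd226, the activating receptor DNAM-1 (2.36, adjusted p = 0.0048), Klrb1b (1.77, adjusted p = 0.017) and Gpr183, an oxysterol receptor (3.69, adjusted p = 0.0211), were higher. The only member of the list of retinoic acid receptor targets and retinoid metabolism past the threshold was Asb2 (5.17, adjusted p = 0.0326), and that list gave adjusted p = 0.973.

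The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14714 genes. Leaving liver NK RARa403 library 1 out of the shared fit, an alternative chosen after seeing the data, gave 290 genes, 188 higher and 102 lower, including all 89. With 1 library fewer the count fell to 35, 55 and 41 without liver ILC1 control 1, 2 and 3, and to 18, 31 and 18 without liver NK control 1, 2 and 3. Of the 40 called genes named for this comparison, those fits kept 18, 24, 19, 12, 14 and 11, and all 6 fits kept 9: Cxcr6, Zfp683, P2rx7, Ccdc136, Sept8, Socs2, Cd226, Cd7 and Trbc2. The highest adjusted p that any of the 40 reached was 0.256, for Zeb2 without liver ILC1 control library 3, and Eomes reached 0.163 without liver ILC1 control library 1.

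Control spleen ILC1s were compared with control liver ILC1s, the same cell type in another organ. Spleen ILC1s had the higher values of the NK-associated genes Klra8 (5.96 ± 1.15 log2 CPM against −0.60 ± 1.21 in liver; SD, n = 3; log2 fold change 7.15, SE 1.62, adjusted p = 1) and Klra4 (6.75, adjusted p = 1). The value was also higher for S1pr1, a sphingosine phosphate receptor for leaving tissue (2.88, adjusted p = 1). Liver ILC1s had the higher values of cell cycle genes such as Spc25, a kinetochore component (−3.55, SE 0.87, adjusted p = 1), Stmn1 (−1.56, adjusted p = 1) and Mcm4, a replication helicase subunit (−0.86, adjusted p = 1). The other genes of smallest p above the minimum level for naming were Cd55, a complement inhibitor (4.49, SE 1.13, adjusted p = 1), and Dmrta1, with no counts in the liver libraries (at least 28.2-fold higher in spleen, adjusted p = 1). No single gene passed by edgeR, where 468 of 14714 genes had an unadjusted p under 0.05 against 735.7 by chance; DESeq2 called 38 genes, 27 higher in spleen, and limma-voom 0. Cxcr6 (log2 fold change −0.86, SE 1.05, adjusted p = 1), Zfp683 (−1.33, adjusted p = 1), Eomes (2.82, SE 0.95, adjusted p = 1) and Tbx21 (−0.00, adjusted p = 1) did not pass. Il7r (0.95), Itga1 (−0.98), Itga2 (0.92), Ncr1 (−0.28), Bcl2 (−0.33), Rara (0.13), Rarg (0.19) and Rarb, with no counts in liver (at least 1.93-fold higher), had adjusted p = 1 as well.

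As lists, 9 of 30 passed with the preset correlation and 0 with an estimated one, with 0 called members in each. Spleen ILC1 control library 1 differed from libraries 2 and 3 in the direction of liver ILC1s, with list means of 5.08 log2 CPM against 5.88 and 5.79 for NK genes, 7.64 against 6.85 and 6.93 for ILC1 genes, and 1.96 against 4.98 and 8.02 for B cell genes, and a wrong label of it was not excluded. The NK list was higher in spleen ILC1s (median log2 fold change 1.32, 22 of 29 genes positive, 2 higher adjusted over the list alone, adjusted p = 4.54e-13, and adjusted p = 0.14 with an estimated correlation). So was the trafficking and adhesion list (median 0.18, adjusted p = 0.00402, and adjusted p = 0.144 with an estimated correlation). The proliferation list was lower (median −1.59, 33 of 36 genes negative, adjusted p = 1.51e-16, and adjusted p = 0.179 with an estimated correlation). So were the ILC1 list (adjusted p = 0.0329, and adjusted p = 0.869 with an estimated correlation) and oxidative phosphorylation (adjusted p = 0.0164, and adjusted p = 0.916 with an estimated correlation). Among markers of other cells, B cell genes were higher in spleen (median 4.25, 10 of 18 adjusted over the list alone, adjusted p = 4.27e-15, and adjusted p = 0.14 with an estimated correlation). So were macrophage (adjusted p = 0.00317, and adjusted p = 0.705 with an estimated correlation) and liver endothelial markers (adjusted p = 0.00618, and adjusted p = 0.317 with an estimated correlation). These differed between the spleen controls. Libraries 1, 2 and 3 had macrophage means of −0.78, 3.08 and 4.53 log2 CPM and endothelial means of 0.79, 1.32 and 4.79. Mitochondrial transcripts were higher as well (median 0.71, adjusted p = 0.0001, and adjusted p = 0.694 with an estimated correlation). Among B cell genes, Ebf1 gave 6.74 (adjusted p = 1) and Igkc, an immunoglobulin constant region with no counts in liver ILC1 controls, at least 371-fold (adjusted p = 1). Cd79a, a B cell receptor component, was at −1.70 log2 CPM, no counts, in spleen ILC1 control library 1 and at 5.48 and 8.20 in libraries 2 and 3.

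The NK, proliferation and B cell lists passed whichever library was left out. The others did not. With replicates 2 and 3 only, which omits spleen ILC1 control library 1, these others passed in the same direction with the preset correlation. There the ILC1 list gave adjusted p = 5.37e-05, oxidative phosphorylation 0.0491 and trafficking 0.00166. Mitochondrial transcripts gave 1.52e-10, macrophage markers 6.84e-11 and endothelial markers 0.000599. The ILC1 list was lost without liver ILC1 control 1 (adjusted p = 0.117) and spleen ILC1 control 2 and 3 (0.234 and 0.571), and oxidative phosphorylation without the same libraries (adjusted p = 0.387, 0.0960 and 0.571). Trafficking was lost without spleen ILC1 control 2 (0.0689) and mitochondrial transcripts without spleen ILC1 control 3 (0.597). Macrophage markers were lost without liver ILC1 control 3 (0.626) and spleen ILC1 control 2 and 3 (0.197 and 0.726). Endothelial markers were lost without liver ILC1 control 2 (0.0860) and spleen ILC1 control 3 (0.726). Without liver ILC1 control 2, edgeR called 1 gene, Cd55 (log2 fold change 8.67, adjusted p = 0.0417). Without liver NK RARa403 library 1 in the shared fit it called 0 genes, with 809 of 16565 at an unadjusted p under 0.05. Replicates 2 and 3 only gave 0 genes too, with 953 of 14192 at that unadjusted p.

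**Figure D3:**
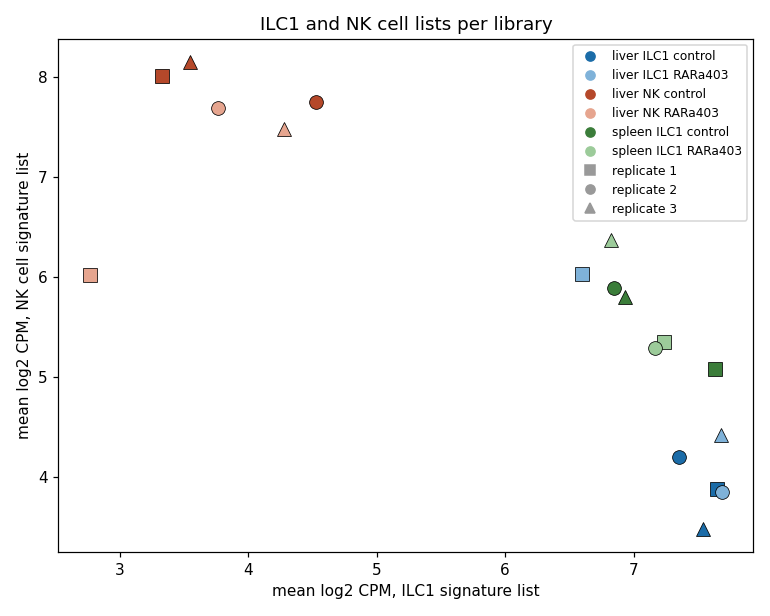
Mean log2 CPM of the ILC1 list (x axis) against that of the NK list (y axis) in each of the 18 libraries, coloured by group. Liver NK libraries lie at 2.77 to 4.53 on the ILC1 axis, ILC1 libraries of both organs at 6.60 to 7.69, and liver ILC1 RARa403 library 1 at 6.60 and 6.02.

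RARa403 was compared with control in liver ILC1s, the comparison closest to the question of the series. The genes that mark ILC1s did not pass the test. This does not show unchanged levels, given standard errors of 1.04 for Cxcr6 and 0.84 for Zfp683. The spread behind these errors was estimated from all 18 libraries, liver NK RARa403 library 1 included. Itga1 and Il7r encode markers of the sort in both genotypes, so their levels are limited by the gate. A set number of sorted cells per library cannot show whether ILC1s were lost. Cxcr6 was 9.86 ± 0.85 log2 CPM in RARa403 and 10.13 ± 0.09 in control cells (SD, n = 3; log2 fold change −0.13, SE 1.04, adjusted p = 1). Zfp683 gave −1.36 (SE 0.84, adjusted p = 1), and Itga1 −0.53 (SE 1.25, adjusted p = 1). Il7r gave 1.32 (SE 0.69, adjusted p = 1) and Tbx21 −0.15 (SE 0.25, adjusted p = 1). Bcl2, an inhibitor of apoptosis, gave 0.12 (SE 0.42, adjusted p = 1), and 30 apoptosis regulators as a list adjusted p = 0.928. The smallest p was that of Klra8, an NK receptor gene (8.15, SE 1.66, adjusted p = 1), at 8.66, 5.97 and −0.76 log2 CPM in the 3 RARa403 libraries and at most 0.68 in the controls. Dmrta1 (at least 37.8-fold higher, adjusted p = 1), Il18r1, a subunit of the interleukin-18 receptor (1.51, SE 0.37, adjusted p = 1), and Plod2, a collagen lysyl hydroxylase (−4.00, SE 1.03, adjusted p = 1), came next among genes above the minimum level for naming. Of the receptors, Rarg gave 1.36 (SE 0.62, adjusted p = 1), and Rarb, with no counts in the controls, was at least 8.51-fold higher (adjusted p = 1). The 17 genes of retinoic acid receptor targets and retinoid metabolism had a median of 0.26 (adjusted p = 0.448). Eomes gave 2.37 (SE 0.94, adjusted p = 1). Rara (0.26), Ncr1 (0.08) and Itga2 (0.80) had adjusted p = 1 too.

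No gene passed by edgeR, with 432 genes at an unadjusted p under 0.05 against 735.7 by chance; DESeq2 called 38, 18 higher and 20 lower, and limma-voom 0. The count remained 0 without liver NK RARa403 library 1 in the shared fit, with 778 of 16565 genes at an unadjusted p under 0.05. The low number of 432 thus depended on a library outside this comparison. It was 1 without liver ILC1 RARa403 library 3, Klra8 (log2 fold change 8.73, adjusted p = 0.00678), and 1 with replicates 2 and 3 only, Gm13394 (3.89, adjusted p = 0.00173), named after its values were seen.

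Of 30 lists, 9 passed with the preset correlation in liver ILC1s and 0 with an estimated one, with 0 called members in each. The proliferation list was lower in RARa403 cells (median log2 fold change −1.46, 32 of 36 genes negative, adjusted p = 1.07e-11, and adjusted p = 0.478 with an estimated correlation), with Stmn1 at −1.62 and Ube2c, a ubiquitin-conjugating enzyme of the cell cycle, at −6.89 (adjusted p = 1 for each). Its mean was 5.53, 5.23 and 4.67 log2 CPM in the controls and 1.79, 4.22 and 3.98 in RARa403 libraries 1, 2 and 3. Cytokines and chemokines were lower (median −0.36, 15 of 17 negative, adjusted p = 0.00314, and adjusted p = 0.478 with an estimated correlation), with the chemokines Ccl4 at −2.49 and Ccl3 at −2.18 (adjusted p = 1 for each). Both lists passed whichever library was left out, but with replicates 2 and 3 only proliferation gave a median of −0.82 (adjusted p = 0.0475) and the cytokine list adjusted p = 0.182. The NK list was higher (median 1.18, 2 of 29 genes higher adjusted over the list alone, adjusted p = 0.000743, and adjusted p = 0.646 with an estimated correlation). Its mean was 6.02 log2 CPM in RARa403 library 1, 3.84 and 4.41 in libraries 2 and 3, and 3.48 to 4.19 in the controls, and without RARa403 library 1 it gave adjusted p = 0.690. On an axis from liver to spleen ILC1s, made after the values were seen, that library lay at 0.569 and spleen ILC1 RARa403 library 1 at 0.384. Libraries 2 and 3, each placed with itself left out, lay at 0.0103 to 0.363 in liver and 0.653 to 0.819 in spleen. The ILC1 list did not pass (median −0.06, adjusted p = 0.804), at a mean of 6.60 in RARa403 library 1 against 7.69 and 7.68 in libraries 2 and 3.

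The remaining liver ILC1 lists were each lost without more than a single library. Interferon response genes were lower (median −0.52, adjusted p = 0.00741, and adjusted p = 0.698 with an estimated correlation), with Mx1 at −3.10 but Mx2 at 5.98 (adjusted p = 1 for each). They were lost without RARa403 1 (adjusted p = 0.198) and control 2 (0.504). Trafficking and adhesion was higher (median 0.25, adjusted p = 0.0251, and adjusted p = 0.478 with an estimated correlation), with Klf2 at 1.62 and S1pr1 at 1.66 (adjusted p = 1 for each). It was lost without RARa403 1 and 3 (adjusted p = 0.0774 and 0.210) and control 1 and 3 (0.101 and 0.0805). Activating and inhibitory receptors were lower (adjusted p = 0.0421, and adjusted p = 0.718 with an estimated correlation), lost without RARa403 1, 2 and 3 (0.0774, 0.122 and 0.122) and control 1 and 3 (0.0588 and 0.490). Oxidative phosphorylation was lower (median −0.23, adjusted p = 0.0129, and adjusted p = 0.718 with an estimated correlation), lost without RARa403 2 (0.0869) and control 1 (0.377). Hepatocyte markers were lower (adjusted p = 0.00501, and adjusted p = 0.698 with an estimated correlation), lost without RARa403 3 (0.0729) and without control 1 (0.856), the library with the high hepatocyte mean. Ribosomal protein genes were lower (median −0.22, adjusted p = 0.0437, and adjusted p = 0.889 with an estimated correlation), lost without RARa403 1, 2 and 3 (0.0774, 0.146 and 0.0761) and without control 1 (0.0613), where the median turned to 0.14. With replicates 2 and 3 only, the lists no longer past the threshold in liver ILC1s were also the NK list (adjusted p = 0.863), oxidative phosphorylation (0.218), trafficking and adhesion (0.357) and hepatocyte markers (0.614). Ribosomal proteins then had the opposite sign (adjusted p = 0.0413).

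In liver NK cells the smallest p was that of Plcg1, a phospholipase of receptor signalling (log2 fold change −5.62, adjusted p = 0.0788), which lay under the minimum level for naming genes. Above that level the smallest p-values were those of Slfn5, a Schlafen family gene (log2 fold change 8.98, SE 1.91), and Pag1, a membrane adaptor (1.99, SE 0.44). Next were Gimap6, a GTPase of lymphocyte survival (−1.28, SE 0.30), and Kcnj8, a potassium channel subunit (−2.35, SE 0.56), and each of the 4 had adjusted p = 0.428. Gimap6 was 9.89 ± 0.08 log2 CPM in control and 8.49 ± 0.76 in RARa403 NK cells, and Kcnj8 6.94 ± 0.66 and 4.51 ± 0.87 (SD, n = 3). Eomes (−0.04, SE 0.87, adjusted p = 1), Bcl2 (0.10, SE 0.42, adjusted p = 0.986) and Tbx21 (−0.68, SE 0.25, adjusted p = 0.431) did not pass. Rara (2.49, SE 0.77, adjusted p = 0.428) and Itga1 (5.02, SE 1.51, adjusted p = 0.428) had their high values in library 1, at 8.75 and 7.61 log2 CPM, and with replicates 2 and 3 only Rara gave −0.13. Cxcr6 (5.47, SE 1.73, adjusted p = 0.428) had its high value in library 3, at 3.91 log2 CPM and 88 counts, with no counts in libraries 1 and 2. Of the other genes fixed in advance, Il7r gave 1.39 (adjusted p = 0.535), Zfp683 1.85 (adjusted p = 0.609), Ncr1 −0.15 (adjusted p = 0.924), Itga2 0.09 (adjusted p = 1.00), Rarb 0.52 (adjusted p = 0.978) and Rarg −0.25 (adjusted p = 0.945). No gene passed by edgeR, with 1418 at an unadjusted p under 0.05 against 735.7 by chance; DESeq2 called 163, 139 of them higher, and limma-voom 0. With only the NK groups in the fit, the unadjusted count was 200 of 11332 genes. Without RARa403 library 1 it was 539 and 1 gene passed, Plcg1 (−7.64, adjusted p = 0.0253). Without RARa403 library 2 the calls were Slfn5 (9.58, adjusted p = 0.0189) and Snai3 (−6.73, adjusted p = 0.0411), and without library 3 Ifit1bl1 (−4.24, adjusted p = 0.0233). With replicates 2 and 3 only they were Gm13394 (4.19, adjusted p = 0.000848) and Gimap3 (−1.45, adjusted p = 0.0251). Plcg1, Snai3, Ifit1bl1, Gm13394 and Gimap3 were named after their values were seen.

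The only list of 30 that passed in liver NK cells was proliferation, higher in RARa403 cells (median log2 fold change 1.59, 31 of 36 genes positive, 0 past the threshold, adjusted p = 2.34e-05, and adjusted p = 0.868 with an estimated correlation). Cdc20, an activator of the anaphase complex, was at 2.46 and Cdk1 at 4.61 (adjusted p = 0.431 for each). Its mean was 5.16, 2.88 and 2.30 log2 CPM in the controls and 4.69, 6.21 and 4.09 in the RARa403 libraries. Without RARa403 library 1 and with replicates 2 and 3 only the list passed (adjusted p = 1.99e-11 and 1.31e-23), and without RARa403 library 2 it did not (adjusted p = 0.129). The NK list gave a median of −0.25 (adjusted p = 0.160) and the retinoid list adjusted p = 0.759.

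In spleen ILC1s the smallest p-values of RARa403 against control were those of Egr1, an immediate early transcription factor (0.18 ± 1.84 log2 CPM in RARa403 and 6.38 ± 2.28 in control cells; SD, n = 3; log2 fold change −6.57, SE 1.34), and of Kmo, an enzyme of tryptophan breakdown with no counts in RARa403 cells (at least 41.6-fold lower). Npat (−1.76, SE 0.44) and Cd200r2 (−5.51, SE 1.32) came next, and each of the 4 had adjusted p = 1. Cxcr6 (0.31, SE 1.04), Zfp683 (−1.03, SE 0.84), Eomes (0.20, SE 0.88), Il7r (0.61, SE 0.68), Bcl2 (−0.15, SE 0.42) and Rarg (1.57, SE 0.62) also had adjusted p = 1, as had Tbx21 (−0.29), Rara (0.26), Rarb (0.01), Itga1 (−0.48), Itga2 (−0.02) and Ncr1 (0.38). No gene passed by edgeR, with 425 at an unadjusted p under 0.05 against 735.7 by chance; DESeq2 called 25, 11 higher and 14 lower, and limma-voom 0. The count was 0 without liver NK RARa403 library 1 in the shared fit, with 830 of 16565 genes at an unadjusted p under 0.05. It was 1 with replicates 2 and 3 only, Gm13394 (3.88, adjusted p = 0.00163).

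Of 30 lists 5 passed in spleen ILC1s with the preset correlation and 0 with an estimated one, with 0 called members in each. Immediate early and stress genes were lower in RARa403 cells (median −0.40, 24 of 32 negative, 2 lower adjusted over the list alone, adjusted p = 0.00243, and adjusted p = 0.455 with an estimated correlation), with Egr1 and Gadd45b (−1.60, adjusted p = 1) leading. This list passed whichever library was left out, and gave adjusted p = 0.0766 with replicates 2 and 3 only. Proliferation was higher (median 1.48, 34 of 36 positive, adjusted p = 5.4e-06, and adjusted p = 0.639 with an estimated correlation), with Cdc20 at 2.62 and Mki67, the Ki-67 gene, at 2.88 (adjusted p = 1 for each). It was lost without RARa403 library 1 (adjusted p = 0.430), whose mean was 5.91 log2 CPM against 4.34 and 2.20 in libraries 2 and 3 and 2.72 to 3.74 in the controls. Markers of ILC2s and ILC3s were higher (13 of 13 positive, adjusted p = 0.00243, and adjusted p = 0.455 with an estimated correlation), with Il23r at 6.14 and Il1r1 at 2.19 (adjusted p = 1 for each). They were lost without RARa403 library 1 (adjusted p = 0.288). Interferon response genes were lower (median −0.55, adjusted p = 0.00243, and adjusted p = 0.639 with an estimated correlation), with Mx1 at −3.43 (adjusted p = 1). They were lost without RARa403 1 and 3 (adjusted p = 0.288 and 0.0909) and control 2 (0.0780). Liver endothelial markers were lower (7 of 7 negative, adjusted p = 0.00243, and adjusted p = 0.455 with an estimated correlation), with Kdr at least 54.5-fold and Egfl7 at least 14.7-fold lower (adjusted p = 1 for each). They were lost without RARa403 2 and 3 (adjusted p = 0.116 and 0.0563), without control 3 (0.543), and without liver NK RARa403 library 1 in the shared fit (0.0535). That control library had an endothelial mean of 4.79 log2 CPM, against 0.79 and 1.32 in control libraries 1 and 2. With replicates 2 and 3 only, proliferation (adjusted p = 0.0650), interferon response (0.341) and the ILC2 and ILC3 markers (0.504) did not pass either.

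Because no gene passed in any of the 3 RARa403 comparisons, none was shared between them by edgeR. DESeq2 calls in the same direction numbered 5 in liver ILC1s and liver NK cells, 3 in liver and spleen ILC1s, and 2 in liver NK cells and spleen ILC1s. Independent lists would share 0.0945, 0.0152 and 0.0591, and calls in opposite directions numbered 4, 1 and 3. That expectation does not hold if libraries of the same code in different populations come from the same animal, which the labels do not say. The RARa403 effects were also compared directly. Between liver ILC1s and liver NK cells 0 genes differed by edgeR (913 at an unadjusted p under 0.05 against 735.7 by chance; DESeq2 56, limma-voom 0), and without liver ILC1 RARa403 library 3 there was 1, Klra8 (log2 difference 8.91, adjusted p = 0.0388). Among the smallest p-values were those of Plcg1 (log2 difference 5.80, SE 1.02, adjusted p = 0.467), Klra8 (8.32, adjusted p = 0.798) and Copg2 (−2.45, adjusted p = 0.798). Between spleen and liver ILC1s 0 genes differed by edgeR (397 at an unadjusted p under 0.05 against the same number by chance; DESeq2 22, limma-voom 0), with Spc25 (4.97), Cdc20 (4.89) and Klra8 (−7.21) at adjusted p = 1 each. With replicates 2 and 3 only, both interactions gave 0 genes. Without liver NK RARa403 library 1 in the shared fit, spleen against liver ILC1s gave 0 genes, with 869 of 16565 at an unadjusted p under 0.05. The proliferation list separated the effects in both tests. It was lower in liver ILC1s relative to liver NK cells (median difference −3.19, adjusted p = 9.55e-15, and adjusted p = 0.733 with an estimated correlation). It was higher in spleen relative to liver ILC1s (median difference 3.12, 33 of 36 positive, adjusted p = 1.88e-18, and adjusted p = 0.563 with an estimated correlation). Both passed whichever library was left out. With replicates 2 and 3 only, the median differences were −3.46 (adjusted p = 2.28e-22) and 0.78 (adjusted p = 0.00194). RARa403 libraries 1 of liver and spleen ILC1s, whose exchange was not excluded, had list means of 1.79 and 5.91 log2 CPM.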

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

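The interaction tests and their splits were fixed before the data were examined. The tests of scaling, of other cell types and of a few abundant genes, the 3 tests of the liver to spleen axis, the test of the Gimap genes without liver NK RARa403 library 1, and the pooled contrast were chosen only after the result was seen.

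The RARa403 effect on 4 lists differed between liver ILC1s and liver NK cells in a test of the difference itself, with the preset correlation only. These were the NK list, relatively higher in liver ILC1s (median difference 1.26, adjusted p = 7.95e-05, and adjusted p = 0.733 with an estimated correlation), and proliferation, relatively lower (−3.19, adjusted p = 9.55e-15, and adjusted p = 0.733 with an estimated correlation). The others were interferon response, lower (−1.02, adjusted p = 0.0157, and adjusted p = 0.954 with an estimated correlation), and hepatocyte markers, lower (−5.16, adjusted p = 0.0287, and adjusted p = 0.954 with an estimated correlation). The NK list was lost without liver ILC1 RARa403 library 1 (adjusted p = 0.107). Interferon response was lost without liver ILC1 RARa403 1 (0.126), liver ILC1 control 2 (0.279), liver NK RARa403 3 (0.619) and liver NK control 1 (0.0821). Hepatocyte markers were lost without liver ILC1 RARa403 1 and 3 (0.107 and 0.115), liver ILC1 control 1 (0.592), liver NK RARa403 2 and 3 (0.327 and 0.101) and liver NK control 1 and 2 (0.0821 and 0.0525).

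Between spleen and liver ILC1s the effect differed for the NK list, relatively lower in spleen (−0.92, adjusted p = 0.01002, and adjusted p = 0.984 with an estimated correlation), proliferation, higher (3.12, adjusted p = 1.88e-18, and adjusted p = 0.563 with an estimated correlation), and hepatocyte markers, higher (6.25, adjusted p = 0.00884, and adjusted p = 0.984 with an estimated correlation). The NK list was lost without liver ILC1 RARa403 1 (0.796), liver ILC1 control 3 (0.0621), spleen ILC1 RARa403 1 and 2 (0.0522 and 0.124) and spleen ILC1 control 2 (0.0743). Hepatocyte markers were lost without liver ILC1 RARa403 1 and 3 (0.0804 and 0.112), liver ILC1 control 1 (0.687), spleen ILC1 RARa403 1 (0.409) and spleen ILC1 control 3 (0.104). With replicates 2 and 3 only, proliferation gave a median difference of 0.78 (adjusted p = 0.00194) between spleen and liver ILC1s, where RARa403 libraries 1 of liver and spleen had list means of 1.79 and 5.91 log2 CPM. The NK list then gave adjusted p = 0.0605 for liver ILC1s against NK cells and 0.446 for spleen against liver ILC1s, and hepatocyte markers 0.896 and, in the opposite direction, 0.23. For single genes, 57 of 100 splits gave at least the 913 genes at an unadjusted p under 0.05 found for liver ILC1s against liver NK cells (highest other 1141). For spleen against liver ILC1s 87 of 100 splits gave at least the 397 genes found (highest other 928), so chance was not excluded for either count.

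Liver NK RARa403 library 1 stood apart from the other 17 libraries. An effect of RARa403 in NK cells as the whole cause is argued against, because genes over 3 log2 units from the control mean there (1071 higher and 2469 lower) moved in the other 2 RARa403 NK libraries by a median ratio of 0.00899 of its own deviation (SE 0.00160), below the bound of 0.25. For cells of another type, 0 of 10 lists of other cell types had their highest mean in it. The bar was the highest mean in any other library, for B cell genes 8.02 log2 CPM. A smaller share of other cells could not reach that bar, so other cells in this library stay open. Its 20 most abundant genes took 13.3% of its counts against at most 8.39% elsewhere, which may contribute, but that share does not account for single genes missing altogether. The cause of the missing transcripts stays open.

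On an axis that sets the means of libraries 2 and 3 at 0 for liver and 1 for spleen ILC1s (728 genes), spleen control library 1 lay at 0.150, spleen RARa403 library 1 at 0.384 and liver RARa403 library 1 at 0.569, where libraries 2 and 3, each placed with itself left out, lay at 0.0103 to 0.363 in liver and 0.653 to 0.819 in spleen. B cell transcripts are argued against as the source of the position of spleen control library 1. That library lay at 0.2296 without B cell genes (620 genes), with spleen and liver RARa403 libraries 1 at 0.573 and 0.929. The Gimap levels of spleen control library 1 and liver RARa403 library 1 were 0.0486 and 1.24, with control at 0 and RARa403 at 1 (spread 0.374). These levels cannot decide on an exchange of the libraries. The Gimap genes were chosen after they were seen to be lower in RARa403 libraries under the given labels. A shift of the libraries numbered 1 stays open: the spleen ones shifted toward the liver end by −0.608 and −0.304, the liver control by 0.0672, within the spread of 0.110, and only liver RARa403 library 1 toward the spleen end (0.2503, and 0.0660 if exchanged with spleen RARa403 library 1). An exchange of liver and spleen RARa403 libraries 1, which carry the same code and had hepatocyte means of −0.50 and 4.03 log2 CPM, stays open. So do an exchange of spleen control library 1 with liver RARa403 library 1, a wrong label of spleen control library 1 alone and a difference between animals. No biological explanation was tested.

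The mean level of the Gimap family, GTPases that affect lymphocyte survival, was lower in each of the 9 RARa403 libraries than in each control of the same population, with a median log2 change of −0.84 over 8 genes in the pooled contrast. A difference in scaling moves all genes of a library alike. It cannot alter the level of the Gimap genes relative to 1071 genes of similar abundance, whose median was −0.0385. With RLE factors the Gimap median was −0.84 as well. Both kinds of scaling factors centre the genes, so a median near 0 for the similar genes decides nothing. A change of all genes together could not be seen. Liver NK RARa403 library 1 alone cannot account for lower levels in the other RARa403 libraries, and without it the median was −0.70. Because the family was chosen for being lower in RARa403 libraries, that median is no independent test. The Gimap genes and Rosa26 share chromosome 6, so DNA from the strain in which the insert was made was tested as a cause. For the 246 genes between them the odds ratio of an unadjusted p under 0.01 was 0.943 (95% interval 0.191 to 2.83, Fisher's exact p = 1). Only 3 of them were past that p, so an excess up to the upper end of the interval stays open. A variant at the Gimap genes themselves was not tested. The family was chosen after its values had been seen under the real split of the 6 codes. That split was the only 1 of 10 with so low a median (the other 9 ranged from −0.40 to 0.18). Because of the choice this rank is no support, and the splits are too few for a share under 0.05. An effect of RARa403 stays open as a hypothesis, with reads shared between Gimap paralogs also open.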

How the results depend on the processing

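The tests with liver NK RARa403 library 1 out of the shared fit and with replicates 2 and 3 only were chosen only after the result was seen. DESeq2 gave 38 genes for RARa403 in liver ILC1s, 163 in liver NK cells and 25 in spleen ILC1s, 431 for control liver ILC1s against NK cells (88 of the 89 shared), 38 for control spleen against liver ILC1s, and 56 and 22 for the interactions. Without a filter the counts were 43, 523, 32, 355, 78, 268 and 41. These tests ran on 31539 and 32798 genes, and the cause of the larger counts was not tested. For control liver ILC1s against NK cells, limma-voom gave 479 genes (283 higher, 196 lower), only the groups compared 343 (197 higher, 146 lower), liver NK RARa403 library 1 out of the shared fit 290, and replicates 2 and 3 only 221 (118 higher, 103 lower). RLE factors gave 88, the code term 86 and the fold threshold 89.

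Replicates 2 and 3 only gave 1, 2 and 1 genes for RARa403 in liver ILC1s, liver NK cells and spleen ILC1s. Leaving out each library gave 0 to 1, 0 to 2 and 0 to 0 genes there, 18 to 55 for control liver ILC1s against NK cells, 0 to 1 for control spleen against liver ILC1s, and 0 to 1 and 0 to 0 for the interactions. Genes shared in direction between RARa403 comparisons numbered 5, 3 and 2 by DESeq2, and 2, 2 and 2 at an unadjusted p under 0.01 in both, against 0 by the main test. Those of the last kind were Gm13394, Gm43062, Tmem171 and Gimap6, named after their values were seen. The ribosomal protein list in liver ILC1s reversed with replicates 2 and 3 only, to a median of 0.14 (adjusted p = 0.0413), and the cause was not tested. For single named genes 1049 values kept direction and side, 72 were weaker, 52 stronger and 46 moved. For lists 214 kept them, 99 were weaker and 1 reversed. A gene not called in the main test kept its side by staying uncalled. Of 73 such pairs of gene and comparison, 25 were called in at least 1 alternative or leave-one-out fit. Of the 40 called, 9 were kept in every leave-one-out fit.

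The replicate block gave 69 genes for control liver ILC1s against NK cells (64 shared), and 263 with only the 2 groups in the fit. Of the 40 called genes named for that comparison, the block in the fit of all groups kept 30, and 10 no longer passed. For RARa403 in liver NK cells it left 88 genes at an unadjusted p under 0.05 with only the 2 groups in the fit. Deviations of same-numbered libraries correlated by 0.0756, −0.0331 and 0.0417 for RARa403 in liver ILC1s, by 0.0264, −0.00670 and 0.0221 in liver NK cells, by 0.245, 0.0888 and 0.0198 in spleen ILC1s, by 0.102, 0.0729 and 0.0993 for control liver ILC1s against NK cells, and by 0.0925, 0.124 and 0.0163 for control spleen against liver ILC1s, so the numbers were not taken to pair the samples. Within a genotype, however, same-numbered libraries carry the same code, and the Xist and Y chromosome counts largely follow the code in all 3 populations, so they may share an animal. The comparisons between control groups then treat libraries of the same animal as independent. Every library correlated best with its own number only in the comparisons between control groups, a hint from the data and not from the design. Counting error limits levels below 0.334 to 0.860 CPM.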

Other observations

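The pooled RARa403 contrast and the levels given here were chosen only after the result was seen. The mean RARa403 effect over the 3 populations gave 0 genes by edgeR (931 at an unadjusted p under 0.05 against 735.7 by chance; DESeq2 90, limma-voom 12). Without liver NK RARa403 library 1 it gave 8 genes: Gimap6 (−0.91, adjusted p = 0.00494), Gimap4 (−1.02, adjusted p = 0.00494), Plcg1 (−2.77, adjusted p = 0.0174), Nebl (1.96, adjusted p = 0.00705), Cap1 (1.10, adjusted p = 0.00936), Gm13394 (3.44, adjusted p = 0.0188), Plec (0.76, adjusted p = 0.0217) and Pag1 (0.81, adjusted p = 0.0333). For Plcg1 the mean rests mostly on liver NK cells: the main fit gave 0.18 in liver ILC1s, −5.62 in liver NK cells and −0.85 in spleen ILC1s. Replicates 2 and 3 only gave 13 genes. If libraries of the same code share an animal, these p-values are too small, because the test counts such libraries as independent. Of the 10 splits of the 6 codes 5 gave at least 931 genes (highest other 1193), and the splits are too few for a share under 0.05.

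Gm13394, a processed pseudogene (ENSMUSG00000083773), had 452 to 1009 counts in RARa403 libraries 2 and 3 of each population and 19 to 64 in the other 12 libraries, RARa403 library 1 included. Which gene its reads come from is uncertain.

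For each comparison of 3 against 3 libraries the 10 splits are too few for a share under 0.05. For control liver ILC1s against NK cells the real split gave 89 genes, the only 1 of 10 to reach that count, and the highest other 0. At an unadjusted p under 0.05, RARa403 in liver ILC1s gave 432 genes, reached by 4 of 10 splits (highest other 446), in liver NK cells 1418, reached by 5 (highest other 1463), and in spleen ILC1s 425, reached by 5 (highest other 737). Control spleen against liver ILC1s gave 468, reached by 4 (highest other 602).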
